A study of Mus musculus with 8 samples.

How the data were processed

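Gene expression was measured in 8 samples of sorted mouse limb bud cells, 4 of the zone of polarizing activity (ZPA) and 4 of the rest of the limb (non-ZPA). Per the labels, RNA was extracted with silica columns, and biotinylated target was made by a 2-cycle amplification from 50 ng of total RNA. The array type, Mouse430_2, was read from the deposited experiment files. The deposited table held the authors' signal intensity, 1 linear value per probe set and array, for 45101 probe sets, and was made with GCOS 1.3 per the submitters' processing notes. The summary method inside that software and any detection calls were not given in the sources used here. Each deposited intensity column had a mean of 500 after the lowest and highest 2% of values were dropped, so that each array had already been scaled. No column belonged to a sample outside the series. The deposited experiment files held other fields, such as the chip type and the scan record, with no expression values. They were used only for the array type and to see which arrays shared a scan day.

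The columns of ZPA replicates 1 and 2 held the same values with different rounding. They differed by at most 0.5 intensity units, and every other pair of columns differed by at least 11380 units at some probe set. Both columns were taken as 1 array, named ZPA array 1+2, and their mean was counted once. All comparisons therefore used 7 arrays, 3 ZPA and 4 non-ZPA, in place of the 8 samples planned before the data were examined. Which of both replicate numbers the array belongs to was not settled. The experiment file of ZPA replicate 2 had no scan record. Nothing in the labels says that the samples came from separate litters or sorts, and p-values then measure only the spread between these samples, which may be technical.

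Values were used as log2(intensity + 16) with no further scaling, because the trimmed means of the arrays were equal. A fold change on this scale understates the change of low genes. A probe set was tested where it lay above the 40th percentile of its own array in at least 4 of the 8 columns, an intensity between 50.8 and 91.9. The 64 control probe sets were left out, and 27816 probe sets passed. Of the 45037 others, 34945 had 1 gene symbol in the platform annotation, 932 had several and were not named, and 9160 were unnamed here. Gene identifiers of 34741 of the probe sets with 1 symbol were found in the reference table of assembly GRCm38.p6, and 0 symbols differed from it. Each gene was represented by the probe set with the highest mean log2 value, which gave 13341 genes, 5918 of them with more than 1 tested probe set. Among the called genes with more than 1 tested probe set, all probe sets had the same sign for 19 of 35 higher genes and 91 of 173 lower genes. A value below the 40th percentile level was treated as measured. The table carries no background bound.

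Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2-sided), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 18 gene lists and 8 cell type marker lists were fixed before the data were examined and were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the 26 lists. An estimated correlation and the rotation test fry were alternatives. fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The genes named were chosen by a rule fixed before the data were examined. It took Shh, then the 12 higher and 12 lower genes with the largest log2 fold change among those past the test whose groups did not overlap and whose higher group mean lay above the 60th percentile. It also took up to 4 called members of each list, or, where fewer than 2 were called, up to 2 members with the highest level. All members of the Hedgehog, posterior, anterior and HoxA and HoxD lists, and the control probe sets, could be named. Any other gene whose values are given is marked in the text as chosen after they were seen.

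Title numbers of the samples fell into 2 runs, and the recorded scan days gave the same split. Run 1 held ZPA array 1+2 and non-ZPA replicates 1 and 2, and run 2 held replicates 3 and 4 of both groups. The run was used as a block, and each run was fitted alone. Other alternatives were the pseudocount, quantile normalization, median centring, the filter, the rule for the probe set, the replicate number as a block, the variance model, array weights, the threshold, and leaving out each array or replicate number. Counting ZPA replicates 1 and 2 separately, a filter on the 7 distinct arrays, ZPA array 3 as the only ZPA array, and the replicate block with the shared array as replicate 2 were added after the data had been seen.

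The gene test was checked on simulated data of the ZPA and non-ZPA comparison with the 13341 real means and spreads and 200 changed genes over 20 draws. It recovered 3% of genes changed by 1 on the log2 scale, 50% of those changed by 2, 70.5% at 3 and 84% at 4, and 4.48% of its calls were false. In 50 simulated draws of the same 13341 genes, camera found a list shifted by -1 in 100% and called 0.1 of 26 unshifted lists on average. These draws held no correlation between genes and gave each gene 1 spread for both groups. The share of false calls was therefore not checked for ZPA arrays that vary more than non-ZPA arrays. Precision was limited by the number of arrays.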

Results

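Expression was profiled in limb bud cells of mouse embryos at stage E10.5 (days after conception) that were heterozygous for an allele placing a green fluorescent protein (GFP) and Cre cassette at Shh, the gene of the secreted ligand Sonic hedgehog. The limbs were dissociated and sorted by fluorescence into GFP-positive cells, the zone of polarizing activity (ZPA), and GFP-negative cells, the rest of the limb. The ZPA is the posterior mesenchyme that patterns the limb from thumb to little finger through Shh. The series held 4 samples of each kind, but the values of ZPA replicates 1 and 2 differed by no more than rounding and were counted as 1 sample. The comparison therefore rests on 3 ZPA arrays and 4 non-ZPA arrays, and values are means of the deposited signal intensity ± SD with n = 3 and n = 4 unless stated. The median intensity of the arrays ran from 75.2 to 133.

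The signal of the bacterial and phage spike-ins, added in equal amounts by the usual protocol, was not even across the arrays. It was 10.4 times the non-ZPA mean on ZPA array 1+2, 6.82 times on ZPA array 4 and 1.57 times on ZPA array 3, against 0.631 to 1.29 times on the non-ZPA arrays. On the log2 scale the ZPA arrays lay 2.27 above the non-ZPA arrays (exact 2-sided permutation test, p = 0.0286, the smallest that 3 against 4 arrays can give). The Actb ratio of the 3 prime to the 5 prime probe set, a sign of RNA integrity, was 21.6 on ZPA array 4 and 2.04 to 5.37 on the other 6 arrays. The Cre probe sets detect a spike-in that shares its sequence with the Cre of the sorted cells. Their ratio to the bioD spike-in of the same array had a log2 difference of -0.11, ZPA minus non-ZPA (exact 2-sided permutation test, p = 0.371).

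The first question was which genes set the ZPA apart from the rest of the limb. Shh, whose reporter defined the sort, was 18.3-fold higher in ZPA cells (log2 fold change 4.20 ± 0.53 SE, adjusted p = 0.00248), with an intensity of 9855 ± 3179 in ZPA cells and 619 ± 425 in non-ZPA cells. This checks the labels and is not an independent finding. Ano1, a calcium-activated chloride channel, rose most, with a log2 fold change of 4.88 ± 0.60 (adjusted p = 0.00236) and an intensity of 1383 ± 931 against 27.4 ± 22.0, a level below the filter on all 4 non-ZPA arrays. Bmp4, a bone morphogenetic protein ligand, was 8.66-fold higher (8751 ± 4071 against 914 ± 156, adjusted p = 0.00236). Sox9, the transcription factor that starts cartilage formation, was 20.7-fold lower in ZPA cells (130 ± 108 against 2278 ± 724, adjusted p = 0.00304). Met, the hepatocyte growth factor receptor carried by migrating muscle precursors, was 18.9-fold lower (45.5 ± 39.9 against 1115 ± 603, adjusted p = 0.00553).

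In all, 326 of 13341 genes passed the test, 57 of them higher and 269 lower in ZPA cells, and all 326 differed by more than 2-fold with no overlap between the groups. Of all tested genes, 18.3% had groups that did not overlap, where chance gives 5.71%. The other genes with the largest rises by the naming rule were Rhno1 (5.48-fold), the RNA-binding Msi2 (5.15-fold), the nonmuscle myosin Myh9 (4.58-fold), Agbl5 (4.54-fold), Hps4 (4.48-fold), Dlgap4 (4.27-fold), the transcriptional cofactor Lmo2 (4.24-fold), the ribosomal protein gene Rpl37a (4.17-fold) and Gnl2 (3.93-fold). The other largest falls by this rule, which sets a minimum level, were Armc8 (22.2-fold), Samhd1 (18.8-fold), Hoxc5 (16.4-fold), the transcriptional cofactors Eya1 (15.2-fold) and Eya4 (14.7-fold), the imprinted noncoding RNA Rian (13.7-fold), Boll (13.1-fold), the protocadherin Pcdh8 (13.1-fold), the Cxcl12 receptor Ackr3 (12.2-fold) and the actin-associated Synpo (11.4-fold). Adjusted p-values of these 19 genes ran from 0.00236 to 0.0340. Eya1 lay below the filter level on all 3 ZPA arrays. Met, Hoxc5, Boll, Pcdh8 and Ackr3 lay above it on only 1 ZPA array, and Armc8, Sox9, Samhd1 and Eya4 on 2. The sizes of these falls rest in part, and for Eya1 wholly, on ZPA values not shown to be above background. In the lists below, a level under the filter is given only where it held on all 3 ZPA arrays. Only 2 of the 5 tested probe sets of Armc8, 3 of 5 of Myh9, 6 of 8 of Msi2, 2 of 3 of Agbl5, 1 of 2 of Dlgap4, 2 of 3 of Eya1 and 3 of 4 of Rian had the sign of the gene's call. With the run as a block 114 genes were higher and 420 lower. Run 2 alone, 2 arrays against 2, gave 122 and 239, and run 1 alone gave 1244 and 1983, with its lone ZPA array assumed to vary like the 2 non-ZPA arrays. The total of 326 moved to 1725 without ZPA array 1+2, and to 151, 101, 108 and 133 without non-ZPA replicates 1, 2, 3 and 4. The split moved to 690 higher and 1035 lower without ZPA array 1+2, to 107 and 249 without ZPA array 3, and to 35 and 271 without ZPA array 4. All 326 genes kept their sign in each of these fits. Groups that do not overlap fix that outcome in advance, so it is no further support.

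**Figure D1:**
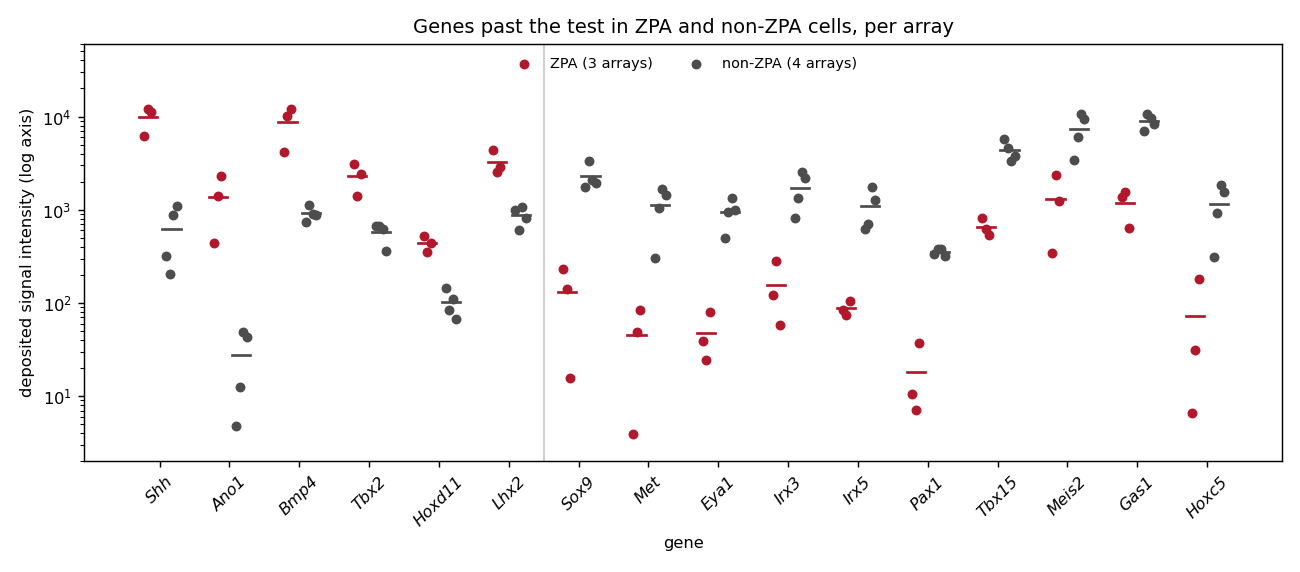
Deposited signal intensity (log axis) of 16 genes past the test, with each array as a point and each group mean as a bar, 3 ZPA arrays in red and 4 non-ZPA arrays in grey. For each gene the points of the groups do not overlap, with Shh at 9855 against 619 on average and Sox9 at 130 against 2278.

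The second question was how genes known for a place or a pathway in the limb were distributed between the groups. Genes of the anterior limb mesenchyme, the side opposite the ZPA, were lower in ZPA cells as a list. Of 12 tested members 5 fell and 0 rose (6 fell when adjusted over the list alone), with a median log2 fold change of -1.30 (camera adjusted p = 6.28e-05, and adjusted p = 0.136 with an estimated correlation). The 5 were Pax1 (11.5-fold lower, 18.4 ± 16.5 against 355 ± 29.0, below the filter level on all 3 ZPA arrays), Irx3 (11-fold), Irx5 (9.81-fold), Asb4 (7.73-fold) and Emx2 (4.53-fold). The other 7 did not pass the test. Epha3 had a log2 fold change of -1.45 (adjusted p = 0.0509) and passed with the run as a block (-1.39, adjusted p = 0.04425). When all probe sets were tested, 1 of its 2 passed as lower. Gli3 had one of -0.68, Alx4 of 0.03 and Lhx9 of 0.61.

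Genes of the proximal limb, next to the body, had the largest list shift, with a median log2 fold change of -2.18 (camera adjusted p = 1.06e-07, and adjusted p = 0.0546 with an estimated correlation). Of 13 members 5 fell and 0 rose (10 fell when adjusted over the list alone). They were Irx3, Irx5 and Emx2, which also stand in the anterior list, with the homeobox gene Meis2 (6.60-fold lower, 1311 ± 1001 against 7361 ± 3245) and Tbx15 (6.49-fold lower, 655 ± 142 against 4374 ± 1085).

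Genes of the posterior mesenchyme were higher in ZPA cells as a list, with a median log2 fold change of 0.72 (camera adjusted p = 0.0233, and adjusted p = 0.293 with an estimated correlation). Of 16 members 2 rose and 0 fell (4 rose when adjusted over the list alone). They were Hoxd11 (3.94-fold, 439 ± 84.8 against 102 ± 33.8, adjusted p = 0.0187) and the T-box repressor Tbx2 (3.81-fold, 2304 ± 858 against 579 ± 146, adjusted p = 0.0168). Both lost their call without non-ZPA replicate 2, 3 or 4. Hoxd13, with a log2 fold change of 2.03 ± 0.77 (adjusted p = 0.171), and Hand2, with 1.52 ± 0.45 (adjusted p = 0.0947), did not pass. With the run as a block, Hoxd13 passed at 2.46 ± 0.30 (adjusted p = 0.00158) and Bmp2 at 2.41 ± 0.40 (adjusted p = 0.00696). Without it Bmp2 was at 1.91 (adjusted p = 0.291). Sall1 at 1.49, Tbx3 at 0.96, Hoxd12 at 0.79 and Grem1 at -1.26 did not pass either. When all probe sets were tested, 1 of the 3 of Tbx3 passed as higher. Hoxd9, at -1.96 (adjusted p = 0.200), passed as lower with the block (-2.32 ± 0.53, adjusted p = 0.03285).

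Genes of the distal limb were higher as a list (median log2 fold change 0.60, camera adjusted p = 0.0109, and adjusted p = 0.233 with an estimated correlation). Of 16 members only the LIM homeobox gene Lhx2 rose (3.67-fold, 3259 ± 973 against 871 ± 210, adjusted p = 0.0120), and 6 rose and 1 fell when adjusted over the list alone. Lhx2 lost its call without non-ZPA replicate 2. When all probe sets were tested, 1 of the 2 of Msx1 and 1 of the 2 of Mycn passed as higher. Both genes were chosen after their values were seen. Of 16 tested genes of the HoxA and HoxD clusters, Hoxd11 rose and Hoxa5 fell (2.67-fold, 893 ± 49.2 against 2463 ± 615, adjusted p = 0.0316). The same 1 and 1 were counted when adjusted over the list alone, and the list did not pass (median log2 fold change -0.13, camera adjusted p = 0.961). Forelimb and hindlimb identity genes were lower as a list (median log2 fold change -1.36, camera adjusted p = 0.0107, and adjusted p = 0.210 with an estimated correlation), with 2 of 8 members past the test, Hoxc5 and Hoxc4 (10.8-fold lower, 53.2 ± 47.3 against 645 ± 154). These 2 also fell when adjusted over the list alone, and Tbx5, chosen after its values were seen, had a log2 fold change of 0.40. The hindlimb members of this list differed between the runs in both groups. The 3 dorsal and ventral patterning genes did not pass (camera adjusted p = 0.885), with a list median of -0.06 and a mean of 0.23. Lmx1b was at 1.49 and Bmpr1a at -0.06.

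Among 13 genes of the Hedgehog pathway and its targets, 1 passed the test. Gas1, a Shh co-receptor, fell 7.85-fold (1187 ± 487 against 8913 ± 1556, adjusted p = 0.00236), with 2 of 3 probe sets of this sign, and 3 genes fell when adjusted over the list alone. The transcriptional targets Ptch1 (log2 fold change 0.94 ± 0.43, adjusted p = 0.262) and Gli1 (0.89 ± 0.45, adjusted p = 0.308) did not pass the test. With the run as a block Ptch1 was at 1.115 ± 0.323 (limma adjusted p = 0.0737) and Gli1 at 0.868 ± 0.457 (adjusted p = 0.309). Cdon, another co-receptor, was at -2.88 (adjusted p = 0.0647), Gli2 at -1.65, Boc at -0.87, Smo at 0.60 and Sufu at -0.46. The list had a median log2 fold change of -0.46 (camera adjusted p = 0.195).

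In the BMP list of 17 genes, Bmp4 rose and its receptor gene Bmpr1b fell (5.27-fold, 60.04 ± 30.7 against 390 ± 206, adjusted p = 0.0233, below the filter level on all 3 ZPA arrays), and 6 rose and 4 fell when adjusted over the list alone. The list median was 0.68 (camera adjusted p = 0.0791), and with the run as a block the list passed (0.70, adjusted p = 0.0299). In the FGF list of 14 genes, the receptor gene Fgfr2 (5.45-fold) and the transcription factor Ets1 (6.03-fold, 3 of 4 probe sets of this sign) fell and 0 rose, with 2 rising and 3 falling when adjusted over the list alone. This list had a median of 0.27 and a mean of -0.04, of opposite sign (camera adjusted p = 0.885). In the Wnt list of 14 genes the secreted inhibitor Sfrp2 fell 3.14-fold (adjusted p = 0.0497), with 1 rising and 3 falling when adjusted over the list alone. Wnt5a was at 0.30 and Lef1 at -0.03. Its median was 0.23 and its mean -0.30, of opposite sign (camera adjusted p = 0.856). Retinoic acid pathway genes were lower as a list (median log2 fold change -0.46, camera adjusted p = 0.0209, and adjusted p = 0.210 with an estimated correlation). Of 9 members 1 passed, the retinoic acid-degrading enzyme Cyp26a1 (4.17-fold lower, 46.7 ± 27.3 against 231 ± 61.4, adjusted p = 0.0482), and 3 fell when adjusted over the list alone. The calls of Cyp26a1 and Sfrp2 ended when any array but ZPA array 1+2 was left out. Neither gene passed when all probe sets were tested. Crabp2, at -1.44 (adjusted p = 0.0512), and Crabp1, at 1.08, did not pass, and with the run as a block Crabp2 passed (-1.55, adjusted p = 0.0135).

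Genes of chondrogenic condensation, the gathering of mesenchyme before cartilage forms, were lower as a list (median log2 fold change -0.68, camera adjusted p = 0.0116, and adjusted p = 0.233 with an estimated correlation). Of 14 members Sox9 and the cadherin gene Cdh2 fell (5.56-fold, 808 ± 495 against 3908 ± 839), with 1 rising and 4 falling when adjusted over the list alone. For Cdh2 only 1 of 2 probe sets had this sign.

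Lists of general cell state did not pass the test. None of 25 cell cycle genes passed by limma, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05. The list median was 0.10 (camera adjusted p = 0.283), and the replication genes Pcna and Mcm7 were at 0.69 and 0.40. Of 12 cell death genes Casp9 fell (3.46-fold, adjusted p = 0.0339; 2 fell when adjusted over the list alone), the list median was -0.05 (camera adjusted p = 0.472), and Bcl2l11 was at -1.18 and Pmaip1 at -2.0. Casp9 lost its call when any array but ZPA array 1+2 was left out. Of 16 hypoxia and glycolysis genes Bnip3 fell (2.63-fold, adjusted p = 0.0302; 1 when adjusted over the list alone), the median was -0.15 (camera adjusted p = 0.856), and Pgk1 was at 0.68 and Ldha at -0.33. None of the 16 cholesterol biosynthesis genes (median 0.23, camera adjusted p = 0.393) and none of the 24 immediate early and stress genes (median 0.05, mean -0.08, camera adjusted p = 0.953) passed by limma, with 5 and 6 genes at an unadjusted p under 0.05. Adjusted over the list alone, 1 rose and 2 fell in the cholesterol list and 0 changed in the stress list. Hmgcs1 was at 1.01, Fdft1 at 0.59, Hspa8 at 1.19 and Ier2 at 0.79.

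Markers of other cell types were set beside these lists, since the GFP-negative sort holds every other cell of the limb. Muscle precursor genes were lower in ZPA cells (median log2 fold change -1.30, camera adjusted p = 6.28e-05, and adjusted p = 0.210 with an estimated correlation). Of 10 members 3 fell, Met, Pax3 (6.39-fold) and Myf5 (8.13-fold, below the filter level on all 3 ZPA arrays), and 5 when adjusted over the list alone. Myf5 lost its call when any array but ZPA array 1+2 was left out. Surface ectoderm genes were lower (median -1.19, camera adjusted p = 8.36e-05, and adjusted p = 0.293 with an estimated correlation). Of 17 members 2 fell, Epcam (7.32-fold, 170 ± 65.2 against 1472 ± 924) and the desmosome gene Dsp (6.35-fold), and 8 when adjusted over the list alone. Erythroid genes were lower (median -1.09, camera adjusted p = 0.00103, and adjusted p = 0.293 with an estimated correlation), with 2 of 12 past the test, the embryonic globin Hba-x (7.88-fold) and Slc4a1 (6.26-fold), and 6 when adjusted over the list alone.

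The remaining marker lists did not pass the test. None of their members passed by limma, which tested 9 genes of the apical ectodermal ridge (median -0.17, camera adjusted p = 0.857), 16 of endothelium (median -0.22, camera adjusted p = 0.885), 9 of neural crest, Schwann cells and neurons (median -0.65, camera adjusted p = 0.276), 6 of pericytes and smooth muscle (median -0.49, camera adjusted p = 0.564) and 13 of macrophages and other leukocytes (median 0.46, camera adjusted p = 0.111). Adjusted over the list alone, 2 fell in the neural list, 1 rose and 2 fell in the pericyte list, and 0 changed in the other 3. At an unadjusted p under 0.05 stood 0 ridge, 1 endothelial, 2 neural, 3 pericyte and 2 leukocyte genes. Rspo2 was at -1.40 and Sp6 at -0.40, Egfl7 at -0.39 and Ramp2 at 0.50, Dcx at -1.93 and Ngfr at -0.65, Pdgfrb at 1.23 and Acta2 at -1.57, and Coro1a at 1.42 and Laptm5 at 0.39. Of these, Dcx (-2.11, adjusted p = 0.0126) and Rspo2 (-1.71, adjusted p = 0.0430) passed with the run as a block. The leukocyte genes were uneven across the ZPA arrays, with a median difference from the non-ZPA mean of 1.95 on ZPA array 4, 0.12 on ZPA array 1+2 and -0.18 on ZPA array 3.

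In all, 10 of the 26 lists passed camera at the preset correlation, and 0 passed with an estimated correlation, where 5 had an unadjusted p under 0.05. With fry 7 passed, 6 of these 10 and the Hedgehog list (lower, adjusted p = 0.03095), while the posterior, chondrogenic, surface ectoderm and erythroid lists did not (adjusted p from 0.0582 to 0.0912). Of the 13 Hedgehog genes 6 had a fold change above 0, among them the targets Ptch1 and Gli1. The fry call therefore does not show that the targets were lower. With the run as a block 11 passed, the same 10 and the BMP list, with medians of -2.22 for proximal, -1.44 for anterior and 0.86 for posterior genes. Within run 1 these were -1.51, -1.28 and 0.36, and of these 3 only proximal passed (adjusted p = 0.00234, against 0.0619 and 0.579). Within run 2 they were -2.27, -1.39 and 1.41, and all 3 passed (adjusted p = 8.47e-10, 6.13e-05 and 0.000791). Over all lists, 5 passed in run 1 and 7 in run 2. Without ZPA array 3 the calls of 6 lists ended. These were the posterior (median 0.59, adjusted p = 0.134), distal (0.50, adjusted p = 0.0708), limb identity (-0.56, adjusted p = 0.0917), retinoic acid (-0.26, adjusted p = 0.0671), chondrogenic (-0.47, adjusted p = 0.0708) and erythroid lists (-1.18, adjusted p = 0.0680). Without ZPA array 1+2 the retinoic acid call ended (-0.39, adjusted p = 0.119).

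**Figure D2:**
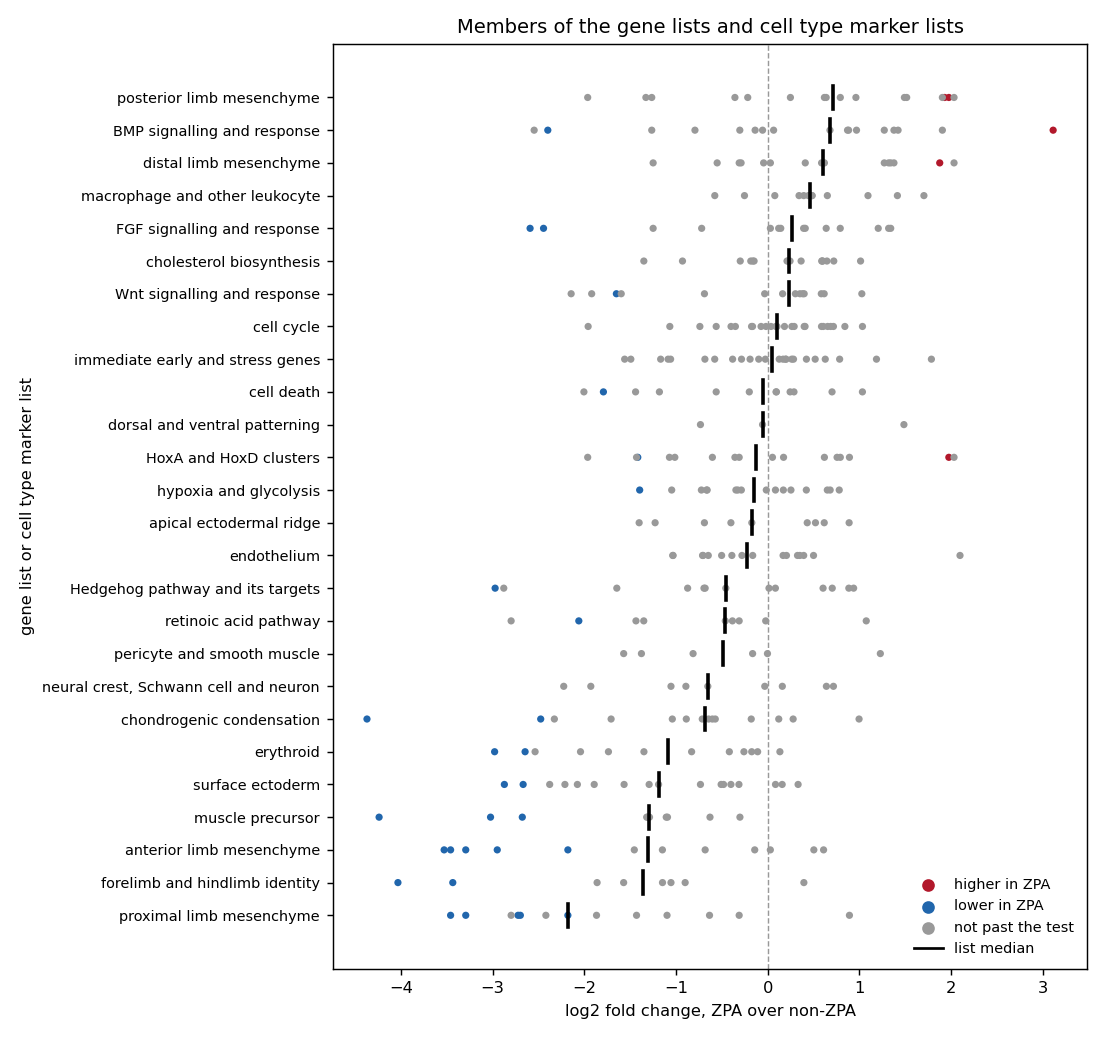
Log2 fold change (ZPA over non-ZPA) of the tested members of the 26 lists, each gene as a point, red where higher and blue where lower past the test, with a black bar at the list median. The medians run from -2.18 for proximal limb mesenchyme to 0.72 for posterior limb mesenchyme.

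**Figure D3:**
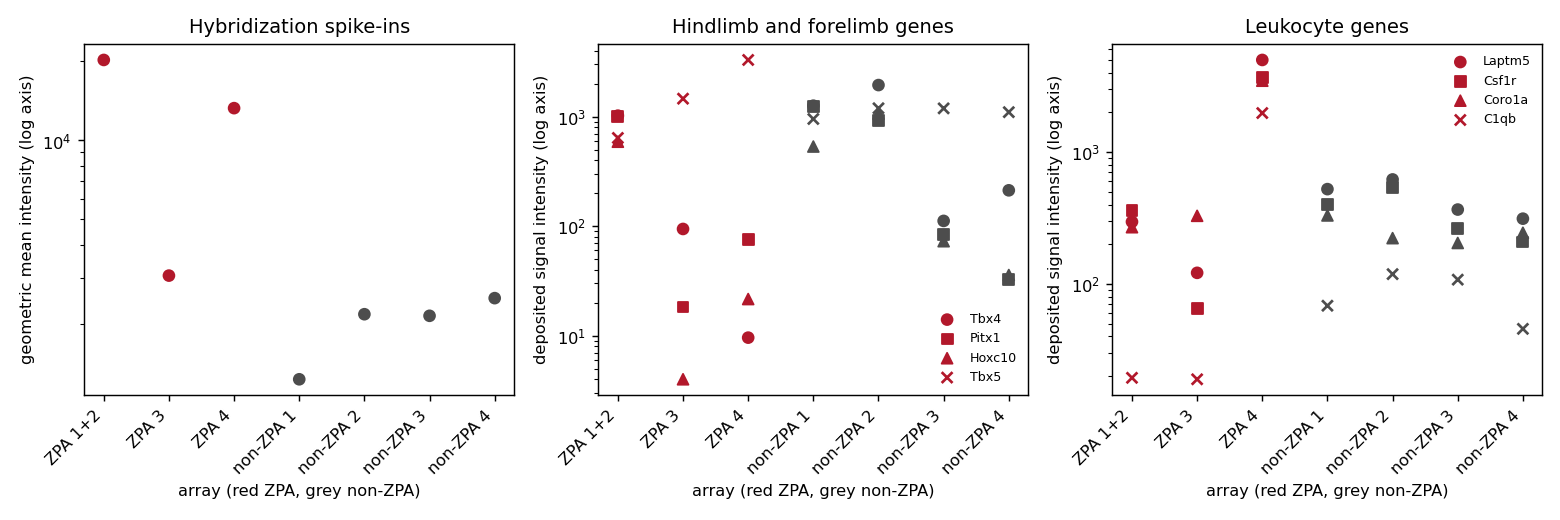
Intensities per array on log axes, ZPA in red and non-ZPA in grey, of the spike-ins (geometric mean of the hybridization controls), of limb identity genes and of leukocyte genes, chosen except for Laptm5 and Coro1a after their values were seen. Spike-ins are 10.4 and 6.82 times the non-ZPA mean on ZPA arrays 1+2 and 4, hindlimb genes are high on the arrays of run 1 (ZPA 1+2, non-ZPA 1 and 2), and leukocyte genes are high on ZPA array 4, with Laptm5 at 4995.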

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

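Of the tests in this part, the hold-out on ZPA array 3 and the splits of the arrays were fixed before their results were seen, and the splits that keep the runs and the tests of 3 prime bias, of scaling, of a general difference between the runs, of limb content and of leukocytes were chosen after. In the non-ZPA arrays, 124 values were tested for a single array far from the other 3, and chance gives about 1 in 20. Only 5 stood apart by Dixon's ratio, each of them a gene. Tbx2 was low on non-ZPA replicate 4 (ratio 0.901, log2 intensity 8.56 against 9.33 to 9.41). Non-ZPA replicate 1 was high for Grem1 (ratio 0.865, 11.06 against 9.28 to 9.52) and Ets2 (ratio 0.874, 12.80 against 12.02 to 12.12), and low for Bmpr1a (ratio 0.8765, 10.87 against 11.98 to 12.14). Myf5 was high on non-ZPA replicate 2 (ratio 0.936, 9.99 against 7.29 to 7.47).

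The spike-in signal, outside the main measurement, lay above every non-ZPA array on all 3 ZPA arrays, at 10.4 times the non-ZPA mean on ZPA array 1+2, 1.57 times on ZPA array 3 and 6.82 times on ZPA array 4. Spike-ins that take more of the scaled signal are consistent with less limb RNA target on these arrays, and 269 genes were lower in ZPA cells against 57 higher. The hold-out asked whether genes lower on the 2 arrays with the most spike-in signal were also lower on ZPA array 3. In it, the 100 genes most clearly lower on ZPA arrays 1+2 and 4 against 2 non-ZPA arrays were also lower on ZPA array 3 against the other 2, with medians from -2.39 to -1.92 (log2) over 6 ways to divide the non-ZPA arrays and a bootstrap upper bound of at most -1.56. The 100 genes most clearly higher gave less on ZPA array 3, with medians from 0.41 to 0.57 and 76% to 86% of them above 0. The hold-out argues against low target on those 2 arrays as the whole cause of the falls of the picked genes. It cannot decide the cause of the excess of lower genes, since genes truly lower in ZPA cells would give the same result. ZPA array 3 also had a spike-in signal above every non-ZPA array. Without ZPA array 4, whose Actb ratio was the highest, 271 genes were lower and 35 higher, and with quantile normalization 258 and 55. This argues against 3 prime bias on that array and against the scaling as the whole cause. Without ZPA array 1+2, which had the most spike-in signal, 1035 were lower and 690 higher. Lower genes then still outnumbered higher genes, but by far less in proportion than the 269 against 57 of all arrays. The comparison that argues against the array of ZPA replicate 4 and the scaling therefore does not clear ZPA array 1+2. That array as the main cause of the excess of lower genes is not excluded. Of the 35 splits of the 7 arrays into 3 and 4, only 1, the real one, gave as many genes, with 326 against at most 3 in the others. This would exclude chance for the gene count only if arrays may be exchanged between the runs. The runs themselves differed, with 16 genes higher and 5 lower in run 1, so that condition is doubtful. The splits that keep the runs number 18, too few for a share under 0.05, and there the real split gave 326 and the highest other 0 (534 and 0 with the run as a block). A difference between a sort of 1 limb region and a sort of all others, which the design names, remains open and was not tested.

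For the lists, chance cannot be excluded even if arrays may be exchanged between the runs. The real split gave 10 lists past the test, and 2 of the 35 splits gave as many, the real one included. The highest of the other splits also gave 10, with ZPA arrays 1+2 and 3 and non-ZPA replicate 1 on one side, a split that follows neither run.

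Hindlimb genes, chosen like Tbx5, Isl1 and Hoxc6 here after their values were seen, separated the runs in both groups. Tbx4 had an intensity of 1021 on ZPA array 1+2, 1259 and 1942 on non-ZPA replicates 1 and 2, and 9.6 to 213 on the 4 arrays of run 2. Tbx4, Pitx1 and Hoxc10 differed between the runs by 3.75 to 4.07 on the log2 scale (run 1 minus run 2). Over all 13341 genes the median difference was 0.005072, with 95% of them from -1.30 to 1.49. These values cannot decide whether a general difference in signal between the runs is the cause. Each array had already been scaled to the same trimmed mean, which tends to keep the median difference small. Tbx4, Pitx1 and Hoxc10 were chosen after their values were seen, so their place outside that range is no test either. A candidate explanation is a larger share of hindlimbs in run 1. Tbx5, a forelimb gene, had a difference of -0.93. It was 639 on the ZPA array of run 1 against 1459 and 3293 on those of run 2, but 952 and 1193 on the non-ZPA arrays of run 1 against 1190 and 1099. Of the same list, Hoxc4 (-0.85) and Hoxc5 (-1.85) were lower and Isl1 (2.06) higher on every array of run 1 in both groups, as that share would give, while Hoxc6 (-0.57) overlapped. Hoxc4, Hoxc5 and Isl1 each lay above the filter level on only 1 ZPA array. Their order within the ZPA group thus rests on values not shown to be above background. On the non-ZPA arrays Isl1 was 122 on replicate 1 of run 1 against 117.9 on replicate 3 of run 2. With the overlap of Tbx5 and Hoxc6, limb content and another difference between the runs cannot be told apart, and the design names no biological group that differs between runs.

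Leukocyte markers were high on ZPA array 4 alone, the array with the Actb ratio of 21.6. The list's median difference from the non-ZPA mean was 1.95 there, above the range of -0.51 to 0.999 for 10000 matched lists. This range cannot serve as a test, because the list and the array were chosen for their high values. The matched lists also ignored the correlation between leukocyte genes, estimated at 0.47. Of the 13 genes of the list, 10 were highest on that array, with Laptm5 at 4995 and Coro1a at 3475. Csf1r was at 3685 and C1qb at 1976, both chosen after their values were seen. The endothelial list, which did not pass the test between the groups, had a median difference of 0.79 there against -0.42 and -0.79 on ZPA arrays 1+2 and 3, and this was not tested. Whether 3 prime bias plays a part in the leukocyte values was not tested either. Scaling of an array with low target was argued against by ZPA array 1+2, which had more spike-in signal and a list median difference of 0.12. Leukocytes in that sorted sample remain a candidate source, although the GFP gate would be expected to remove them. None of the 13 genes stands in another list, and 4 of them lay above the filter level on all 4 non-ZPA arrays, so that limb tissue shows some of this signal. The design names no biological difference between the ZPA arrays, and none was tested.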

How the results depend on the processing

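The main counts were 326 genes, 57 higher and 269 lower, and 10 lists. All 326 genes kept their sign in every setting with 1 value per gene in which they were measured (321 with the 60th percentile filter). Groups that do not overlap fix this sign in advance where arrays are only left out, blocked or weighted. The same holds where only the pseudocount, the variance model or the threshold changes. The gene counts stayed within 1.5 times of the main counts with pseudocounts of 1 and 64, quantile normalization, median centring, no filter, the 60th percentile filter and a filter on 3 of 7 arrays. Given as total, higher and lower, they were 172, 35 and 137 with the mean of all probe sets, 175, 31 and 144 without the intensity trend, and 1233, 384 and 849 with array weights. They were 86, 10 and 76 at an adjusted p under 0.01, 72, 5 and 67 with treat at a fold of 1.5, and 890, 262 and 628 with ZPA replicates 1 and 2 as separate samples. With ZPA array 3 as the only ZPA array, assumed to vary like the non-ZPA arrays, they were 768, 211 and 557. Over all probe sets 106 were higher (484 in total). With the run as a block they were 534, 114 and 420, including all 326. Run 1 alone gave 3227, 1244 and 1983 with 5 lists, and run 2 alone 361, 122 and 239. Same-numbered arrays of both groups correlated at -0.02 to 0.08 in their deviations, and the other pairs at -0.10 to 0.07. No pairing by number was seen. Deviations from the means of 3 and 4 arrays cannot exclude it. The replicate block gave 286, 49 and 237 with the shared ZPA array as replicate 1 and 603, 128 and 475 as replicate 2. Shh stayed between 3.56 and 4.57 in 30 settings. Leaving out an array or a replicate number gave 0 to 1725 genes, 0 to 690 higher and 0 to 1035 lower, 4 to 11 lists, and 3.78 to 4.56 for Shh (adjusted p 0.000859 to 0.0917). The 0 came from limma without replicate 3 of both groups, with 2357 genes at an unadjusted p under 0.05; ZPA array 3 is then gone, and Shh lost its call (adjusted p = 0.0917). Of 51 called genes by the naming rule, 26 kept their call whichever array was left out. Dlgap4, Sfrp2, Cyp26a1, Casp9 and Myf5 lost theirs when any array but ZPA array 1+2 was left out. With an estimated correlation 0 lists passed camera, against 7 with fry (6 of the 10 and Hedgehog). In 3 cases the sign reversed into a call: Evx2 at 1.79 and Bcl2l11 at 1.16 in run 1 alone, and Laptm5 at -1.73 with only ZPA array 3. Where fewer arrays or another threshold do not explain a change, the cause was not tested. Without detection calls, signal over background limits what low values show.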

Other observations

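The gene names in this part, except those already given, were chosen after their values were seen, as was the test of symbol families. Among lower genes outside the lists, the growth factor Igf1 had a log2 fold change of -3.39, and the binding protein Igfbp3 of -2.81. Hgf, the ligand of Met, was at -2.77, and Cxcl12, a ligand of Ackr3, at -2.70, with 2 of 3 probe sets of this sign. Ntn1 was at -4.06, with 1 of 2 probe sets of this sign and a ZPA mean of 5.77, under the filter level. Among higher genes outside the lists, the peptide hormone gene Cck had a log2 fold change of 3.34 from a non-ZPA mean of 13.45, under the filter level, the sodium channel gene Scn11a 2.67 and the Wnt inhibitor Apcdd1 1.61, with 5 of 6 probe sets of this sign. Each of these passed the test at the same threshold as the other genes.

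Genes were also grouped by the letters that start their symbols, which gave 227 families of at least 8 tested genes. By camera at the preset correlation, the families Rpl and Rps, mostly cytosolic ribosomal protein genes, were higher in ZPA cells, with a median log2 fold change of 0.93 for 23 Rpl genes (adjusted p = 4.37e-08) and 0.87 for 27 Rps genes (adjusted p = 0.00042). With an estimated correlation neither passed (adjusted p = 0.938 for both). Of these 50 genes, 6 were kinases or binding proteins with the same letters. With quantile normalization the Rpl and Rps medians were 0.26 and 0.07 (camera adjusted p = 0.133 and 0.859), and with median centring 0.95 and 0.89. The shift thus shrank with quantile normalization and not with median centring. The 47 Mrpl genes of the mitochondrial ribosome had a median of 0.41 (adjusted p = 0.000398, and 0.938 with an estimated correlation) and of 0.48 with quantile normalization (adjusted p = 1.26e-05), but were at -0.04 on ZPA array 1+2 against 0.62 and 0.67 on the other ZPA arrays. The 29 Mrps genes of the same ribosome, with a median of 0.39, did not pass camera (adjusted p = 0.155, and 0.0172 with quantile normalization). The 10 Ndufb genes of respiratory complex I had a median of 0.57 (adjusted p = 0.0304, 0.100 with quantile normalization and 0.938 with an estimated correlation), and were at -0.20 on ZPA array 1+2 against 0.52 and 1.20 on the others. The 12 Ndufa genes (median 0.50, adjusted p = 0.292) and the 21 Cox genes (median 0.33, adjusted p = 0.164) did not pass camera. The 10 Fzd genes, Wnt receptor genes apart from the antisense gene Fzd10os, all had a fold change below 0, with a median of -0.76 (adjusted p = 0.0430, 0.102 with quantile normalization and 0.938 with an estimated correlation), and 0 of them passed the test alone by limma (3 at an unadjusted p under 0.05). None of the 227 families passed camera with an estimated correlation, where 4 had an unadjusted p under 0.05.

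Hoxd13 and Bmp2 also differed between the runs. With the group in the model, Hoxd13 was 2.53 ± 0.30 (SE) higher in run 1 on the log2 scale (limma adjusted p = 0.00594) and Bmp2 2.99 ± 0.40 (adjusted p = 0.0125), and 16 genes were higher and 5 lower in run 1 overall. The reason for these differences between runs was not tested.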
